A study of Mus musculus with 181 samples.

How the data were processed

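Counts were the expected counts of the RSEM gene results as deposited, 1 file per library, rounded to whole numbers. Between 14.7% and 21.1% of all gene values in a library, zeros included, were more than 1e-09 from a whole number before rounding, the form of fractional read assignment. Per the submitters' processing notes, expected counts came from RSEM 1.3.0 on the mouse genome build GRCm38.p6. Per the sample records, tissue was taken from frozen brain in a cryostat, RNA was purified with the RNeasy Mini kit, and libraries were made from 200 ng of total RNA with TruSeq Stranded mRNA reagents. The aligner, the annotation release and the strand setting of the counting step are not given in the sources used here. Gene positions and types were taken from GENCODE vM21 on the same build, in which 55141 of 55401 gene identifiers (99.5%) were found. Gene names are those of that release.

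Each region and age was fitted on its own with all 3 genotypes in edgeR. Genes were kept by filterByExpr with its defaults, libraries were scaled by TMM, dispersions were estimated with the robust option, and tests were quasi-likelihood F tests with the robust option. KO and HET were each compared with WT. The change of the KO difference with age was tested per region as the KO difference at 12 weeks minus that at 4 weeks in 1 fit of both ages. Adjusted p-values are Benjamini-Hochberg over the genes of a comparison, and a gene was called below 0.05. Log2 fold changes were given by edgeR, and their SE was the log2 fold change divided by the square root of the F statistic. The sharing of genes between KO and HET was not analysed here, because it was set to need 20 calls on both sides and no HET comparison had them.

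Gene lists were 39 sets of markers of regions and cell types and of functional groups, written down by symbol. Each was tested by camera in limma with a preset correlation between genes of 0.01 and again with the correlation estimated per list, and the p-values were adjusted over 924 tests. The count of list members adjusted over the list alone uses Benjamini-Hochberg on the members' p-values. Named genes were chosen by rule from those called with an average log2 CPM of at least 1, leaving out Akap11, predicted gene models, Xist, Tsix and Y-linked genes: up to 5 up and 5 down in KO, 3 and 3 in HET, 3 and 3 for age, up to 10 recurrent genes and up to 4 members per list, ordered by fold change or, for lists, by p. Further genes of the lists named because they were called, and Prkar1a outside somatosensory cortex, were chosen after their values were seen. Some genes and 1 list that met these rules are not reported here.

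The fits, filters, lists and comparisons, the alternatives of no filter, RLE scaling, DESeq2, a replicate-number block, an estimated correlation and leaving out each library in turn were set before the data were examined. The alternatives chosen after the data were seen were leaving out the 10 libraries whose Akap11 level went against the label and leaving out the 9 libraries with shifted region markers. The first set holds libraries labelled KO above, or labelled WT below, the lowest HET library of the same region and age. The second holds libraries whose own-region markers lay more than 0.7 log2 units below the median of the region and age, or whose markers of another region lay more than 3 above it, from log2 CPM with a prior count of 2. The test of striatum against the other 5 regions was also chosen after the data were seen. No library was left out of the values given unless stated, and no label was changed.

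The procedure was tested on simulated data made from the mean CPM of each gene over all libraries of the fit and its estimated dispersion. Counts were drawn independently for each gene and library. The simulated libraries thus held no shift in tissue content and no correlation between genes. The shares found need not hold for the real libraries, which had shifted markers. At a fold of 1.5 and of 2, edgeR called 41% and 71% of the changed genes for KO striatum at 4 weeks (17884 genes) and 59% and 76% for KO hippocampus at 12 weeks (19055 genes). For KO striatum at 12 weeks without the libraries against their label it called 32% and 64% (18151 genes), and for the age difference in striatum 27% and 53% (18742 genes). Unchanged genes called were 8, 7, 3 and 4 by edgeR and 29, 34, 28 and 14 by DESeq2.

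Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not analysed here, and neither were transcript-level values.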

Results

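The data are 181 bulk RNA-seq libraries, stranded and poly(A)-selected, from 6 brain regions of mice carrying 0, 1 or 2 disrupted copies of Akap11. The regions were prefrontal cortex, somatosensory cortex, hippocampus, striatum, thalamus and substantia nigra, each at 4 and 12 weeks of age in wild-type (WT), heterozygous (HET) and homozygous (KO) mice. Akap11 encodes a scaffold that binds the regulatory subunits of protein kinase A (PKA), and rare truncating variants of the human gene have been tied to schizophrenia and bipolar disorder. The questions asked here were which genes differ between genotypes in each region, and whether the difference changes with age. Groups held 5 libraries except WT hippocampus at 4 weeks (6), WT prefrontal cortex at 4 weeks (4), HET somatosensory cortex at 4 weeks (6), KO striatum at 4 weeks (4) and WT thalamus at 4 weeks (6). Summed counts ran from 19407782 to 69996628 per library, and 22096 to 26790 genes had counts above 0. Replicates are separate samples by their labels. The labels do not say whether they are separate animals or whether several regions came from the same mouse, so the p-values measure the spread between samples only. Adjusted p-values are from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over all genes tested in a comparison, and a gene was called at adjusted p < 0.05. Counts of genes at unadjusted p < 0.05 in a comparison are given with their percent of the genes tested. By chance alone a share of about 0.05 of the genes tested would reach it. Values are CPM (counts scaled to the total of the library as adjusted by its TMM factor) as mean ± SD. Log2 fold changes are against WT with their standard errors (SE).

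Akap11 followed the genotype label at 4 weeks in all 6 regions and at 12 weeks in prefrontal cortex, hippocampus and thalamus. At 4 weeks the striatum held 360.1 ± 32.5 CPM in WT (n = 5), 196.7 ± 11.1 in HET (n = 5) and 19.9 ± 3.0 in KO (n = 4). The other WT, HET and KO means at 4 weeks were 271.8, 154.9 and 15.7 CPM in prefrontal cortex, 228.2, 120.5 and 12.7 in somatosensory cortex, 288.0, 162.5 and 19.6 in hippocampus, 232.8, 121.3 and 13.7 in thalamus, and 226.6, 119.6 and 15.2 in substantia nigra. At 12 weeks they were 258.7, 133.0 and 17.0 CPM in prefrontal cortex, 275.7, 143.5 and 20.1 in hippocampus, and 195.8, 113.9 and 15.7 in thalamus. Across these 9 KO comparisons the log2 fold change of Akap11 ran from -3.65 (SE 0.11, thalamus at 12 weeks) to -4.17 (SE 0.11, striatum at 4 weeks), and the gene was called in each. In HET it ran from -0.78 (thalamus at 12 weeks) to -0.96 (prefrontal cortex at 12 weeks) and was called in 8 of the 9. The exception was the hippocampus at 4 weeks (-0.83, SE 0.13, adjusted p = 0.109, n = 5 and 6), where DESeq2 gave an adjusted p of 1.87e-05.

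At 12 weeks, 10 libraries of somatosensory cortex, striatum and substantia nigra held an Akap11 level that went against their label, always with replicate numbers 1 or 3. In somatosensory cortex the libraries labelled KO 1 and KO 3 held 197.8 and 233.6 CPM, and those labelled WT 1 and WT 3 held 14.3 and 14.6. In striatum the libraries labelled KO 1 and KO 3 held 299.6 and 312.7 CPM, and those labelled WT 1 and WT 3 held 19.5 and 20.4. In substantia nigra the library labelled KO 1 held 246.1 CPM and the library labelled WT 1 held 17.9. All 181 labels were kept as given. The log2 fold change of Akap11 in KO was therefore -0.51 (SE 0.98) in somatosensory cortex, -0.69 (SE 0.97) in striatum and -1.42 (SE 0.86) in substantia nigra at 12 weeks, none of them called, and it was -3.97, -4.09 and -3.62 without these libraries. In HET it was -0.22, -0.28 and -0.56, and -0.90, -0.97 and -0.85 without them.

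**Figure D1:**
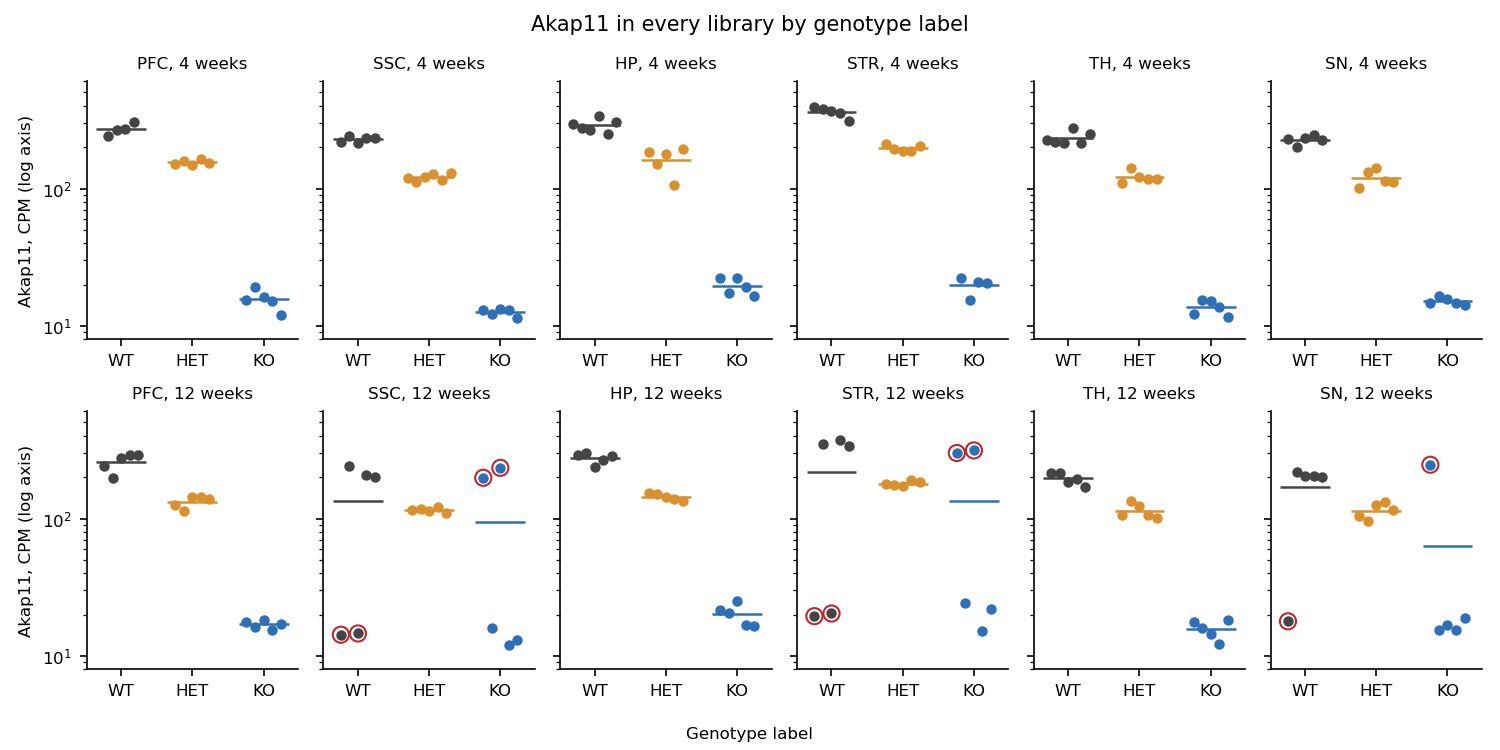
Akap11 in every library, by region, age and genotype label. Lines are group means and rings mark the 10 libraries whose level went against the label.

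Marker genes of each region placed 9 libraries, all at 4 weeks, past the bounds used here for a shifted tissue content. The bounds were chosen after the data were seen, and scores are in log2 units from the median of the region and age. In striatum the libraries labelled KO 2, KO 4 and WT 6 were higher in cortical excitatory neuron markers by 4.96, 4.63 and 3.93, and their striatal projection neuron markers were at -0.95, -0.77 and -0.33. In thalamus the library labelled WT 4 was at -1.13 in thalamic markers and higher in hypothalamic, hippocampal and cortical markers by 7.21, 3.80 and 3.54, and WT 5 was at -0.95 in thalamic markers. In substantia nigra the dopamine neuron markers were at -2.25 in KO 4, -3.18 in KO 6 and -3.89 in WT 3. Thalamic markers were higher in KO 4 and WT 3 by 3.87 and 4.26. In hippocampus the library labelled HET 5 was at -1.25 in hippocampal markers. Libraries within the bounds also departed from the median. Among them, striatal markers in somatosensory cortex were higher by 2.66 and 1.9 in HET 6 and HET 2 at 4 weeks and by 1.97 in HET 5 at 12 weeks. Cortical markers in striatum at 4 weeks were higher by 2.21 in HET 4 and 1.42 in HET 2.

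**Figure D2:**
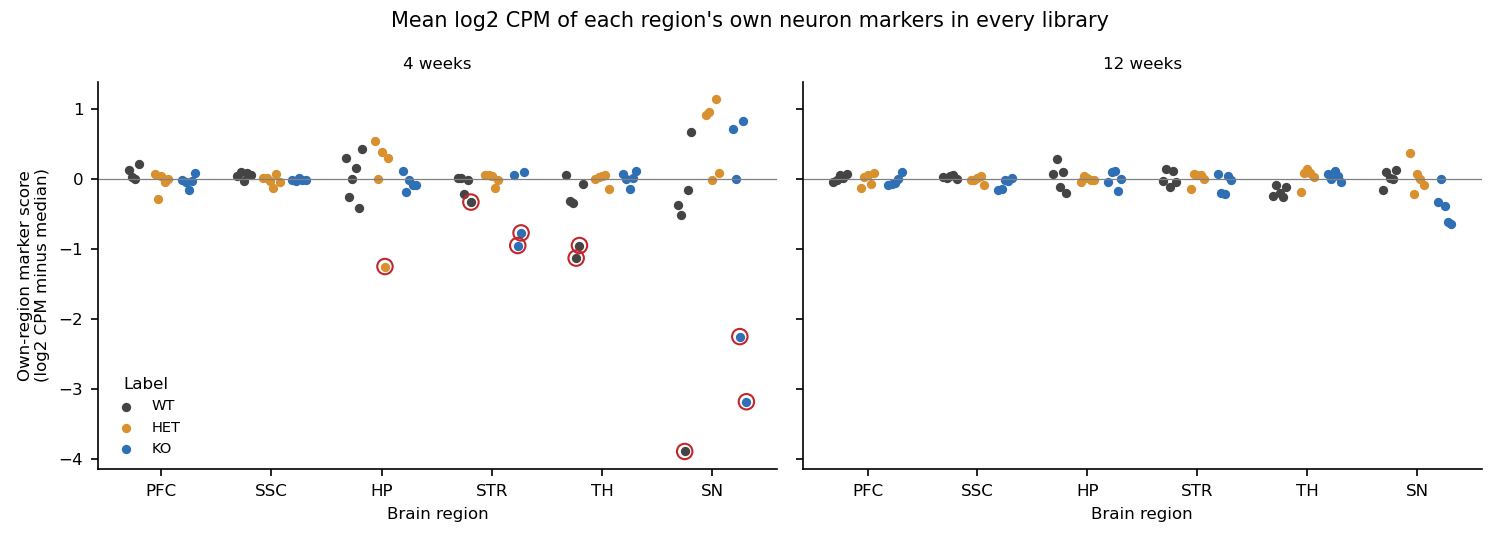
Own-region marker score of every library, as the mean log2 CPM of the markers minus the median of the region and age. Rings mark the 9 libraries with shifted markers.

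More genes were called in the KO striatum at 4 weeks (n = 4 and 5) than in any other comparison. Egr2, an immediate-early transcription factor, fell from 40.45 ± 18.3 to 3.235 ± 1.527 CPM (log2 fold change -3.63, SE 0.45, adjusted p = 0.000804). Htr4, a serotonin receptor that raises cAMP, fell by -2.81 (SE 0.26, adjusted p = 5.14e-05), and the growth factor gene Fgf3 by -2.87 (SE 0.42, adjusted p = 0.00207). Tagln, which encodes a smooth muscle actin-binding protein, fell by -2.38 (SE 0.21, adjusted p = 3.51e-05) and the protease gene Tmprss6 by -2.10 (SE 0.33, adjusted p = 0.00304). Nrip3, a gene of little-known function, rose from 28.44 ± 8.292 to 83.24 ± 8.827 CPM (1.56, SE 0.17, adjusted p = 0.000183). Gng4, a G protein gamma subunit, rose by 1.35 (SE 0.14, adjusted p = 0.00011), and the noncoding RNA Mir670hg by 1.62 (SE 0.22, adjusted p = 0.000898). In all, 725 of 17884 genes were called, 394 up and 331 down, against 483 without the expression filter and 1411 by DESeq2. Without the 3 libraries with shifted markers (n = 2 and 4) 520 were called, 303 of them the same genes. The count fell to 409 without KO 2, 420 without WT 1, 454 without WT 3 and 346 without WT 5.

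Single members of the lists for cAMP signalling, activity and synapses were among the 725, and the lists of adenylyl cyclases and phosphodiesterases (1 of 20 called, adjusted p = 0.197), other A-kinase anchoring proteins (1 of 10, 0.288), activity-regulated genes (8 of 26, 0.608) and postsynaptic density genes (4 of 23, 0.0613) did not pass. The adenylyl cyclase gene Adcy1 rose by 0.84 (adjusted p = 0.00349) and the opioid peptide gene Pdyn by 0.75 (adjusted p = 0.0159), while Akap5, another PKA scaffold, fell by -0.44 (adjusted p = 0.0151). Among activity-regulated genes, Egr1 (-0.77), Homer1 (-0.63) and Inhba (-1.11) fell, and the neuropeptide and secretory genes Pcsk1 (1.06), Scg2 (0.51) and Vgf (0.57) rose, as did the cAMP-responsive gene Crem (0.46). Snap25 (0.54), Syp (0.82, and 0.52 without the shifted libraries), Vamp2 (0.37) and Sv2a (0.37), which encode synaptic vesicle and release proteins, rose, as did Gabra5 (0.92), which encodes a receptor subunit. Of the postsynaptic genes, Shank3 (-0.60), Lrrtm1 (-0.72) and Camk2b (-0.35) fell. Without the 3 libraries with shifted markers (n = 2 and 4) Pdyn (0.77), Egr1 (-0.62), Homer1 (-0.45), Pcsk1 (1.13), Scg2 (0.39), Gabra5 (0.56) and Camk2b (-0.26) were not called. The astrocyte water channel gene Aqp4 fell by -0.70 (adjusted p = 0.000391) and the microglial complement gene C1qb by -0.29 (not called without the shifted libraries, -0.26). Etnppl (1.39, SE 0.33, adjusted p = 0.0323), an astrocytic lipid enzyme gene, was not called without the shifted libraries (1.03, adjusted p = 0.238). Sphkap, which encodes a PKA-binding protein, rose by 1.25 (SE 0.32, adjusted p = 0.0481) and by 0.45 without them (adjusted p = 0.0122). Leaving out single libraries ended the call of Etnppl in 8 of 9 cases and of Sphkap in 6 of 9, and both calls ended without the expression filter.

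**Figure D3:**
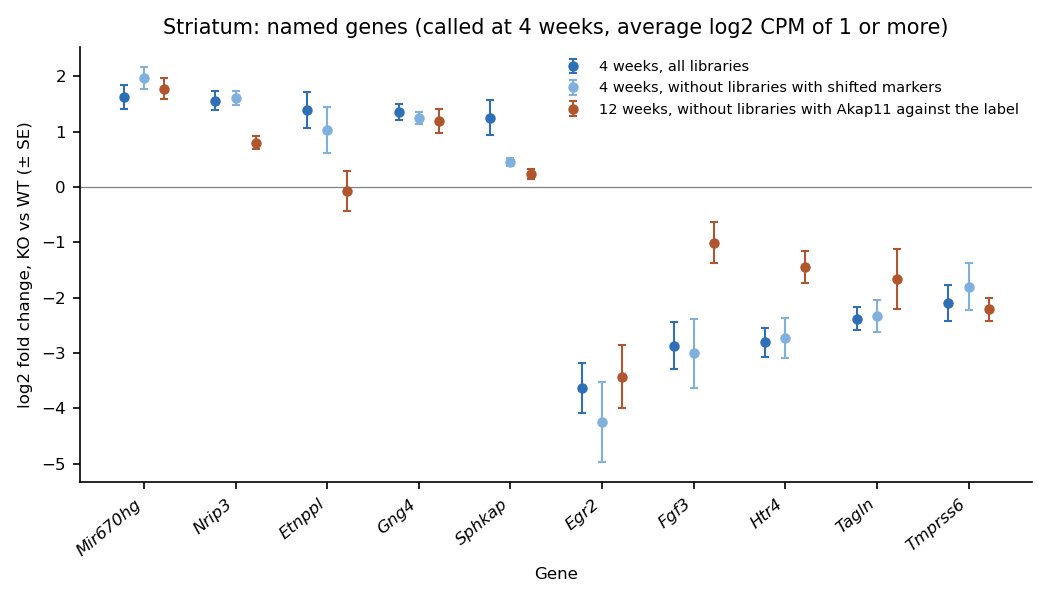
Log2 fold change in KO striatum with SE of 10 named genes at 4 weeks, the 5 largest rises and 5 largest falls among called genes with an average log2 CPM of at least 1, predicted gene models and Akap11 left out. They are shown at 4 weeks with all libraries, at 4 weeks without the libraries with shifted markers, and at 12 weeks without the libraries whose Akap11 level went against the label.

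As groups in the KO striatum at 4 weeks, presynaptic vesicle genes were higher (median log2 fold change 0.364, 5 of 20 called, 11 adjusted over the list alone; camera adjusted p = 6.29e-09, adjusted p = 0.785 with an estimated correlation). GABAergic interneuron markers were higher (median 0.364, adjusted p = 0.000313; adjusted p = 0.401 with an estimated correlation), with Sst at 0.54 and Lhx6 at 0.32 called (0.39 and 0.35 without the shifted libraries, not called), and so were proteasome subunits (0.073, adjusted p = 0.00893; 0.891 as the adjusted p with an estimated correlation). Lower groups were meningeal fibroblast markers (-0.562, adjusted p = 5.09e-05), red blood cell genes (-3.266, adjusted p = 0.000836), mural cell markers (-0.223, adjusted p = 0.000927), endothelial markers (-0.266, adjusted p = 0.00906), microglia markers (-0.206, adjusted p = 0.000163), astrocyte markers (-0.107, adjusted p = 0.0204) and mitochondrially encoded genes (-0.31, adjusted p = 0.0101). With an estimated correlation the adjusted p of these 7 was 0.729, 0.798, 0.798, 0.885, 0.85, 0.877 and 0.879. The haemoglobin genes of the red blood cell list were low, with Hbb-bs at 7.618 ± 6.581 CPM in WT and 0.7859 ± 0.6694 in KO. Cortical excitatory neuron markers, the content that was high in 3 libraries, had a median of 2.106 (adjusted p = 0.0545). Striatal projection neuron markers were lower with all libraries (-0.24, adjusted p = 0.00271; 0.891 as the adjusted p with an estimated correlation) and turned higher without the shifted libraries (0.099, adjusted p = 0.000842; 0.8745 as the adjusted p with an estimated correlation). Without them the presynaptic median was 0.127, and microglia markers (-0.133, adjusted p = 0.0658) and red blood cell genes (-3.073, adjusted p = 0.0752) were not called. The libraries kept still differed in cortical markers, with WT 4 and WT 5 at 0.99 and 0.2 above KO 1 and KO 5 at -0.81 and -0.74.

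In the KO striatum at 12 weeks 0 of 17908 genes tested were called by edgeR with all labels as given, 390 (2.18%) had an unadjusted p < 0.05, and DESeq2 called 3. Without the 4 libraries labelled KO 1, KO 3, WT 1 and WT 3, 199 genes were called (72 up, 127 down, n = 3 and 3). Egr2 fell by -3.43 (adjusted p = 0.0251), Htr4 by -1.45 and Tmprss6 by -2.21. The extracellular matrix and growth factor binding genes Abi3bp (-2.59, adjusted p = 1.33e-06) and Igfbp6 (-2.33, adjusted p = 3e-07) fell. At 4 weeks these 2 were called only without the shifted libraries, Abi3bp at -2.48 (-0.687 with them) and Igfbp6 at -3.04 (-0.745 with them). Also lower at 12 weeks were the peroxidase gene Gpx6 (-2.38) and the lipid-binding gene Sec14l3 (-2.65). Mir670hg rose by 1.77 (adjusted p = 0.000608), Gng4 by 1.19, Nrip3 by 0.80 (adjusted p = 0.00644), the G protein beta subunit gene Gnb4 by 1.45, the hyaluronan synthase gene Has3 by 1.43 and Epha10 by 1.39. Etnppl (-0.08), Sphkap (0.23), Fgf3 (-1.01) and Tagln (-1.66) were not called. Gabra5 rose by 1.06 and Syp by 0.38, and Camk2b fell by -0.38 and Inhba by -1.35. Snap25 (0.02) and Aqp4 (-0.19) were not called. Striatal projection neuron markers were lower (median -0.154, adjusted p = 3e-05; 0.885 as the adjusted p with an estimated correlation). With all labels as given, interferon-stimulated genes were higher (0.229, adjusted p = 0.00086; 0.768 as the adjusted p with an estimated correlation), which was 0.061 without the 4 libraries (adjusted p = 0.65). Mitochondrially encoded genes were lower with all labels (-0.257, adjusted p = 1.3e-07; 0.795 as the adjusted p with an estimated correlation). With all labels, KO 1, KO 3, WT 1 and WT 3 held Akap11 near the level of the opposite label, so this is a difference between labels.

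The striatal changes were shared between ages when the 4 libraries were left out at 12 weeks. Of 17576 genes tested at both ages, 721 were called at 4 weeks and 197 at 12 weeks, and 90 at both. All 90 had the same direction, 36 up and 54 down, against 3.94 expected in the same direction by the product of the proportions called, summed over up and down. Of the 721, 87.8% had the same sign at 12 weeks, against 60.6% of all genes tested. At 4 weeks without the shifted libraries 91 genes were shared.

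**Figure D4:**
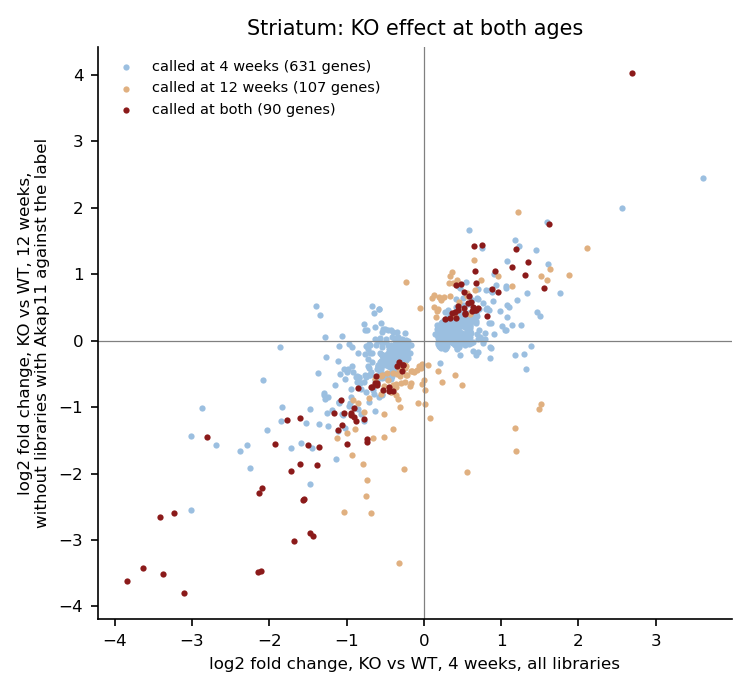
Log2 fold change in KO striatum at 4 weeks against 12 weeks, the latter without the libraries whose Akap11 level went against the label. Colours mark genes called at 4 weeks, at 12 weeks and at both.

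The KO change at 4 weeks in striatum was tested against the mean KO change of the other 5 regions in 1 fit, a comparison chosen after the data were seen. The fit treats the samples of different regions as independent and holds no term for the animal, so its p-values do not account for regions taken from the same mouse. Nrip3 differed by 1.61, Mir670hg by 1.54 and Gng4 by 1.37, while Egr2 differed by -2.70 and Tagln by -2.46. Prkar1a, a PKA regulatory subunit gene, differed by 0.33 (adjusted p = 0.000599). Etnppl (0.84, adjusted p = 0.326), Sphkap (1.43, 0.0655), Fgf3 (-1.72, 0.189), Htr4 (-1.93, 0.11), Tmprss6 (-1.76, 0.231) and Akap11 itself (-0.14, 0.575) were not called. In all, 692 genes were called (529 higher and 163 lower in striatum), 314 of them among the genes called in striatum, and 375 (230 and 145), 168 of them among the genes called in striatum, without the shifted libraries.

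In prefrontal cortex at 12 weeks (n = 5 and 5) Sccpdh, an enzyme gene of lipid droplets, fell in KO from 139.7 ± 12.24 to 104.1 ± 6.556 CPM (-0.43, SE 0.06, adjusted p = 0.0237). It and Akap11 were the 2 genes called, with 902 (4.74%) at unadjusted p < 0.05 and 14 called by DESeq2. Sccpdh was not called without any of KO 1, KO 3, KO 4, WT 3, WT 4 or WT 5, which left 1 gene, and 5 were called without KO 5. At 4 weeks (n = 5 and 4) Akap11 was the 1 gene called by edgeR, with 2586 genes (13.94%) at unadjusted p < 0.05 and 175 called by DESeq2. The count was 105 (30 up, 75 down) without KO 6, 3 without KO 4 and 2 without WT 4. With KO 6 and WT 4 exchanged between the groups it was 2067, which points to a structure of the samples apart from genotype. How the list changes at 4 weeks relate to it was not tested. At 4 weeks presynaptic vesicle genes were lower (median -0.143, adjusted p = 1.12e-05; 0.798 as the adjusted p with an estimated correlation), with Pclo at -0.34 (SE 0.08) and Syp at -0.23 (SE 0.07). Astrocyte markers were higher (0.225, adjusted p = 0.000341; 0.85 as the adjusted p with an estimated correlation), with the glutamate transporter gene Slc1a3 at 0.31 (SE 0.11). At 12 weeks oligodendrocyte precursor markers were lower (-0.207, adjusted p = 1.39e-05; 0.401 as the adjusted p with an estimated correlation) and activity-regulated genes were higher (0.289, adjusted p = 0.00681; 0.881 as the adjusted p with an estimated correlation). None of the genes in these 4 lists was called over all genes tested.

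In somatosensory cortex at 4 weeks (n = 5 and 5) Prkar1a, which encodes a PKA regulatory subunit, fell in KO from 532.3 ± 29.02 to 451.5 ± 6.192 CPM (-0.24, SE 0.04, adjusted p = 0.0483). Frmd6, an upstream regulator of the Hippo pathway, fell by -0.61 (SE 0.10, adjusted p = 0.0483) and the transcriptional corepressor gene Irf2bp2 by -0.50 (SE 0.08, adjusted p = 0.0434). With Akap11 these were the 4 genes called, against 56 by DESeq2. Prkar1a and Frmd6 were not called without the expression filter (adjusted p = 0.0665 and 0.0935). The count was 1 without KO 2, KO 4, KO 5, WT 2, WT 4 or WT 6, 2 without KO 1 or WT 5, 14 without KO 3 and 34 (1 up, 33 down) without WT 1. Activity-regulated genes were lower (median -0.401, 0 called over all genes, 13 of 26 adjusted over the list alone; adjusted p = 4.46e-18, 0.474 as the adjusted p with an estimated correlation). Arc, an immediate-early gene of synapses, was at 417.9 ± 145.1 CPM in WT and 107.3 ± 40.51 in KO (-1.96, SE 0.31, adjusted p = 0.0605), and Npas4 was at -1.38 and Nr4a1 at -1.28. Red blood cell genes were lower in the same comparison (-2.406, adjusted p = 2.5e-05; 0.729 as the adjusted p with an estimated correlation). Oxidative phosphorylation genes were higher (0.065, adjusted p = 2.93e-10; 0.877 as the adjusted p with an estimated correlation).

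At 12 weeks in the KO somatosensory cortex edgeR called 0 genes with all labels as given, with 413 (2.23%) at unadjusted p < 0.05 and 1 called by DESeq2. Akap11 was the 1 gene called without the 4 libraries labelled KO 1, KO 3, WT 1 and WT 3. Ribosomal protein genes were higher (0.122, adjusted p = 7.96e-22; 0.798 as the adjusted p with an estimated correlation), with Rps6 at 0.33 and Rpl10 at 0.57, and the median was 0.191 without the 4 libraries. Cortical excitatory neuron markers were lower (-0.098, adjusted p = 0.00511; 0.565 as the adjusted p with an estimated correlation) and were not called without them (adjusted p = 0.108).

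In hippocampus at 4 weeks (n = 5 and 6) genes of striatal projection neurons were higher in KO. Rgs9, a regulator of G protein signalling, was at 20.35 ± 5.332 CPM in KO and 10.92 ± 2.704 in WT, and the receptor genes Adora2a and Drd2 were at 1.79 (SE 0.39) and 1.04 (SE 0.28). The list had a median of 0.653 (adjusted p = 2.61e-16; 0.401 as the adjusted p with an estimated correlation), with 0 of 28 called over all genes and 14 adjusted over the list alone. Markers of other tissue moved with it: thalamic markers were higher (0.326, adjusted p = 0.00464; 0.877 as the adjusted p with an estimated correlation), cortical excitatory neuron markers lower (-0.34, adjusted p = 0.0108; 0.795 as the adjusted p with an estimated correlation), and dopamine neuron markers had a median of 0.445 (adjusted p = 0.0731). Among WT libraries, WT 5 was also above the median of the region and age in striatal (0.47) and thalamic (1.14) markers, and WT 2 was above every KO library in thalamic markers (1.64, against at most 0.99). Microglia markers were lower (-0.128, adjusted p = 3.43e-05; 0.798 as the adjusted p with an estimated correlation), with P2ry12 at -0.30. Red blood cell genes had a median of -2.352. Akap11 was the 1 gene called, with 1692 (8.83%) at unadjusted p < 0.05 and 22 called by DESeq2, and 3 were called without WT 5. At 12 weeks (n = 5 and 5) interferon-stimulated genes were higher (0.433, 17 of 19 positive, adjusted p = 9.21e-08; 0.795 as the adjusted p with an estimated correlation), with Oas1a at 1.37 and Ifit1 at 0.96. Postsynaptic density genes were lower (-0.096, adjusted p = 4.58e-05; 0.798 as the adjusted p with an estimated correlation). Thalamic markers were higher in the same comparison (0.665, adjusted p = 0.000274; 0.85 as the adjusted p with an estimated correlation), with library scores of -1.63 to 1 in KO and -1.16 to 0.23 in WT. Akap11 was again the 1 gene called, with 590 (3.1%) at unadjusted p < 0.05 and 4 called by DESeq2, and 4 were called without KO 5.

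In thalamus at 4 weeks (n = 5 and 6) Col18a1, a basement membrane collagen gene, rose in KO from 16.25 ± 3.504 to 45.97 ± 12.75 CPM (1.5, SE 0.22, adjusted p = 0.0445). It was not called without the libraries labelled WT 4 and WT 5 (1.32, adjusted p = 0.169), nor without the expression filter (adjusted p = 0.0636). GABAergic interneuron markers were lower (median -2.711, adjusted p = 9.21e-08; 0.565 as the adjusted p with an estimated correlation), with Gad1 at 323.4 ± 240.9 CPM in WT and 13.59 ± 5.892 in KO, and the median was -2.459 without WT 4 and WT 5. Hypothalamic neuropeptide genes moved with them (-3.893, adjusted p = 0.00455; 0.785 as the adjusted p with an estimated correlation), with library scores of 0.45 to 7.21 in WT and -0.64 to 0.18 in KO. Thalamic markers were higher (0.386, adjusted p = 1.15e-06; 0.786 as the adjusted p with an estimated correlation), which was 0.115 without WT 4 and WT 5. Akap11 and Col18a1 were the 2 genes called, with 2629 (14.48%) at unadjusted p < 0.05 and 316 called by DESeq2. The count was 1 without KO 2, KO 3, KO 4, KO 5, WT 2, WT 3, WT 4 or WT 5, and 176 (69 up, 107 down) without WT 1. Without WT 4 and WT 5 together it was 3, with Ccl21b and Gm10591 at the same value of 4.77. These 2 chemokine genes are near-identical copies, so which of them changed is uncertain. At 12 weeks (n = 5 and 5) thalamic markers were higher (0.198, adjusted p = 2.1e-08; 0.401 as the adjusted p with an estimated correlation), with Ntng1 at 0.23. Striatal projection neuron markers had library scores of 0 to 0.66 in WT and -0.27 to 0.06 in KO (list median -0.057, adjusted p = 0.526). PKA subunits and inhibitors were lower (-0.144, adjusted p = 0.00145; 0.729 as the adjusted p with an estimated correlation), with Prkar1a at -0.18 and Prkar2b at -0.40. Akap11 was the 1 gene called, with 1228 (6.8%) at unadjusted p < 0.05 and 13 called by DESeq2, and 5 were called without KO 5.

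In substantia nigra at 12 weeks (n = 5 and 5) dopamine neuron markers were lower in KO (median -0.414, 0 called over all genes, 13 of 15 adjusted over the list alone; adjusted p = 5.68e-21, 0.556 as the adjusted p with an estimated correlation). Th, the enzyme gene for dopamine synthesis, was at 872.4 ± 105.4 CPM in WT and 611.1 ± 158.0 in KO, and Aldh1a1 was at -0.47 and Slc18a2 at -0.49. The median was -0.505 without the libraries labelled KO 1 and WT 1. Thalamic markers were higher in the same comparison (0.255, adjusted p = 0.00606; 0.565 as the adjusted p with an estimated correlation). Endoplasmic reticulum chaperones were higher (0.196, adjusted p = 6.96e-06; 0.798 as the adjusted p with an estimated correlation), with Creld2 at 0.46 and Hspa5 at 0.28. With all labels as given edgeR called 0 genes, with 1404 (7.3%) at unadjusted p < 0.05 and 45 called by DESeq2, and 1 was called without WT 1. Without KO 1 and WT 1 together (n = 4 and 4) 7 genes fell: Akap11, the villin-like gene Vill (-1.19), Fam210b (-0.68), the nicotinic receptor subunit gene Chrna3 (-0.63), Nwd2 (-0.63), the AMPA receptor-associated gene Gsg1l (-0.56) and Pmepa1 (-0.41).

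In substantia nigra at 4 weeks (n = 5 and 5) interferon-stimulated genes were higher in KO (median 0.81, 0 called over all genes, 10 of 19 adjusted over the list alone; adjusted p = 4.47e-14, 0.729 as the adjusted p with an estimated correlation). Ifit3, an antiviral effector gene, was at 17.73 ± 10.44 CPM in KO and 8.709 ± 1.592 in WT, and Usp18 was at 1.85 (SE 0.59). Postsynaptic density genes were lower (-0.301, adjusted p = 2.91e-07; 0.795 as the adjusted p with an estimated correlation), with Gria2 at -0.31. Thalamic markers were lower in the same comparison (-0.692, adjusted p = 0.00593; 0.877 as the adjusted p with an estimated correlation). Without the shifted libraries the medians were 0.952, -0.288 and -1.218 for the interferon-stimulated, postsynaptic and thalamic lists, and dopamine neuron markers were higher (0.632, adjusted p = 6e-06; 0.85 as the adjusted p with an estimated correlation). Of the libraries that remained, WT 1 and WT 2 stood apart in thalamic markers (1.95 and 2.68, against -0.45 to 0.38 for the others) and were the lowest in dopamine neuron markers (-0.37 and -0.52, against -0.16 to 0.83), and the comparison was not run without these 2. Akap11 was the 1 gene called, with 1048 (5.61%) at unadjusted p < 0.05 and 16 called by DESeq2. Without the shifted libraries 2 genes were called, Akap11 and Gm16867, a gene in a stretch of near-identical copies whose assignment is uncertain. The KO libraries left out, KO 4 and KO 6, were the only ones of the comparison with Gm16867 above 0 (15.04 and 9.7 CPM), so this call follows from which libraries were left out.

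In HET, Akap11 was the 1 gene called in prefrontal cortex at both ages, in somatosensory cortex and striatum at 4 weeks, in hippocampus at 12 weeks, in thalamus at both ages and in substantia nigra at 4 weeks. In thalamus at 12 weeks it was not called without HET 1, HET 4, HET 5, WT 1 or WT 2, which left 0, and in thalamus at 4 weeks 53 genes (3 up, 50 down) were called without WT 1. Unadjusted p < 0.05 was reached by 373 genes (2.09%) in HET striatum at 4 weeks and by 1521 (8.42%) in HET thalamus at 12 weeks. DESeq2 called 104 genes in HET thalamus at 4 weeks, 20 in HET thalamus at 12 weeks and at most 33 elsewhere. Where edgeR called 0 genes, unadjusted p < 0.05 and the DESeq2 count were 1409 (7.35%) and 33 in hippocampus at 4 weeks. At 12 weeks they were 288 (1.56%) and 2 in somatosensory cortex, 540 (3.02%) and 2 in striatum, and 585 (3.04%) and 1 in substantia nigra. Without HET 2 the somatosensory cortex count was 1.

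The KO change differed between ages for 1 gene, in striatum with all labels as given. Gpcpd1, a glycerophosphocholine phosphodiesterase gene, had a KO change lower at 12 weeks than at 4 weeks by -0.46 (SE 0.08, adjusted p = 0.0429). It was not called without the libraries whose Akap11 level went against the label (-0.47), nor without those with shifted markers (-0.46), nor without the expression filter (-0.46). The striatum count was 0 without any of KO 2, KO 4, WT 1, WT 4 or WT 5 at 4 weeks or KO 1, KO 2, KO 3, KO 4, WT 1, WT 3, WT 4 or WT 5 at 12 weeks. It was 3 without KO 1, 53 (3 up, 50 down) without KO 5 and 19 (1 up, 18 down) without WT 6 at 4 weeks, and 2 without KO 5 at 12 weeks. Unadjusted p < 0.05 was reached by 1773 genes (9.46%) in striatum, and DESeq2 called 104 (30 up, 74 down). In the other regions edgeR called 0 genes for the age difference. Unadjusted p < 0.05 and the DESeq2 count were 948 (4.81%) and 6 in prefrontal cortex, 587 (3.05%) and 2 in somatosensory cortex, and 748 (3.76%) and 2 in hippocampus. They were 1209 (6.41%) and 3 in thalamus, and 1486 (7.49%) and 16 in substantia nigra. In thalamus 1 gene was called without KO 3 or WT 1 at 4 weeks, and in substantia nigra 1 without KO 4 at 4 weeks.

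Akap11 was the only gene called in the same direction in several of the 12 KO comparisons, down in 9. Over the 39 gene lists in 24 comparisons, 246 of 924 tests passed with the preset correlation of 0.01 and 0 passed with an estimated correlation, so the directions of the lists are given above as descriptions of the samples.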

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

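The tests of explanations below were chosen after the patterns were seen, and each prediction was written before its test was run except that on mixed RNA, which was written after. Of 108 groups and measures checked for a library far from the others, where chance alone marks about 1 in 20, 5 were marked. The total of KO 2 in prefrontal cortex at 4 weeks was 68.26 M counts, against 33.74 to 34.47 for the others, and that of KO 5 in substantia nigra at 12 weeks was 34.15 against 48.14 to 52.66. Akap11 was at 246.1 CPM in the library labelled KO 1 and at 17.9 in the library labelled WT 1 of substantia nigra at 12 weeks. The dopamine neuron marker score of WT 3 in substantia nigra at 4 weeks was -3.89, against -0.52 to 0.67 for the others. A change between groups was marked for Gpcpd1, whose KO change in striatum differed by -0.46 between ages, and for the 692 genes whose KO change in striatum differed from the other regions at 4 weeks.

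Akap11 went against the genotype label in 10 libraries at 12 weeks. Scored on the 386 genes called up and 321 called down in KO striatum at 4 weeks with chromosome 14 left out, 4 of the 4 striatal libraries in question lay nearer the mean of the opposite label, with KO 1 and KO 3 at 1.26 and 1.31, WT 1 and WT 3 at 2.05 and 2.09, and the other KO and WT means at 2.1 and 1.27. Labels or samples exchanged between WT and KO libraries would give this. All 4 scores lay within the bounds of the other libraries of the opposite label (KO 2.04 at lowest, WT 1.32 at highest). This argues against a change of Akap11 alone in these 4. Grouped by Akap11 level, the striatal libraries gave 626 called genes, against 0 by label. Nothing in the labels tells whether samples or labels were exchanged, and another biological cause was not tested. In 5 of the 5 libraries labelled WT, Akap11 was at or below the highest of the other KO libraries of the region and age, which speaks against a mixture with RNA of the other genotype in these. Of the 5 labelled KO, 3 lay below the lowest other WT library, in striatum 299.6 and 312.7 against 337.2 CPM and in somatosensory cortex 197.8 against 201.1, so a small share of other RNA in them was left open.

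The 725 genes called in KO striatum at 4 weeks were weighed against 3 technical explanations, and a difference in how KO and WT samples were collected was not tested. The genes called higher were higher in WT cortex than in WT striatum by a median of 0.47 log2 units (0.12 for those called without the libraries with shifted markers, and 0.59 for those called higher at 12 weeks without the libraries in doubt), and those called lower were at -0.57 against -0.02 for all genes tested. These medians lie on both sides of the bound of 0.5 written beforehand and decide little. Without the shifted libraries 520 genes (290 up, 230 down) were called, 303 of them among the 725 and in the same direction. In cortical markers the libraries kept were at -0.81 and -0.74 (KO 1 and KO 5) and at -0.68, -0.67, 0.99 and 0.2 (WT 1, WT 3, WT 4 and WT 5). Cortical content was thus not higher in the KO libraries kept, which speaks against it as the whole source of the 303. The other calls among the 520 do not bear on it, since cortical content still differed. The cortical markers had a median log2 fold change of 2.106 with all libraries, and a share from cortical tissue was left open. With every library thinned to the smallest total, 700 genes were called (360 up, 340 down), which speaks against library size. Of the genes called at 4 weeks outside chromosome 14, 87.8% had the same sign at 12 weeks against 59.4% of those not called, which speaks against an effect of the 4-week libraries alone.

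Entpd4, Entpd4b and Gm16867 on chromosome 14 were lower in KO on average. Entpd4 and Entpd4b are near-identical copies, and Gm16867 overlaps Entpd4 on the opposite strand, so their separate values are uncertain. The KO libraries of the 9 comparisons with labels not in question differed among themselves: Gm16867 was at 8.61 CPM or more in KO 1, KO 4 and KO 6 and at most 0.09 in the others at 4 weeks, and at 4.57 or more in KO 5 and at most 0.11 in the others at 12 weeks. At 4 weeks KO 1 lay above KO 4, at 54.05 and 19.95 in somatosensory cortex and 69 and 35.24 in thalamus. Other genotypes varied too. In somatosensory cortex at 4 weeks WT 1 was at 22.52, against 37.22 to 47.41 in the other WT libraries. HET 5 was at 48.89, against 20.15 to 22.76 in the other HET libraries. The Gm16867 level thus did not follow the Akap11 genotype alone. The sum of the 3 genes was lower in KO in 9 of the 9 comparisons, by a mean of -0.74 log2 units (-0.46 to -0.94), which speaks against reads moving among these 3. Gm27177, which overlaps Entpd4b, was not in the sum. It was lower with an unadjusted p < 0.05 in 5 of the 9, with a mean log2 fold change of -1.32. Of the 178 other genes within 20 Mb of Akap11, 2.25% had an unadjusted p < 0.05 in 1 direction in at least 4 of 9 comparisons, against 0.46% of 18719 genes elsewhere (Fisher exact p = 0.0104), and outside the cluster the share was 1.71% (Fisher exact p = 0.0498). This is consistent with strain variation around the targeted gene, for which sequence variants were not analysed here.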

How the results depend on the processing

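RLE scaling moved none of the counts of called genes by over 1.5 times, and its largest median shift over all genes was 0.014 log2 units. Of 89 results tracked, 55 were a gene in 1 comparison and 34 a list in 1 comparison. Akap11 in each of the 24 genotype comparisons was among the 55. In all, 30 results kept their direction and side of the threshold under every alternative run on them, which was not all alternatives for each. All 30 are gene results, since the 34 lists were weaker with an estimated correlation. How many of the 30 were Akap11 is not given here. Without the expression filter the KO counts were 2 in prefrontal cortex at 4 weeks, 483 in striatum at 4 weeks and 1 in thalamus at 4 weeks, and the age difference in striatum was 0.

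DESeq2 moved most counts of called genes, and the cause was not tested. In the simulated data for KO striatum at 4 weeks it called 58 and 76 of 100 genes changed by 1.5 and 2 fold, with 29 unchanged genes. There edgeR called 41 and 71, with 8 unchanged. For KO hippocampus at 12 weeks DESeq2 called 67 and 82 with 34 unchanged, and edgeR 59 and 76 with 7. The higher counts of DESeq2 may thus hold more false calls. In KO at 4 weeks DESeq2 called 175 genes in prefrontal cortex, 56 in somatosensory cortex, 22 in hippocampus, 1411 (797 up, 614 down) in striatum, 316 in thalamus and 16 in substantia nigra. In KO at 12 weeks it called 14, 1, 4, 3, 13 and 45 in the same order. In HET it called 2, 6, 33, 3, 104 and 2 at 4 weeks and 2, 2, 4, 2, 20 and 1 at 12 weeks. For the age difference it called 6, 2, 2, 104, 3 and 16.

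Without the 10 libraries whose Akap11 level went against the label, KO at 12 weeks had 1 call in somatosensory cortex, 199 in striatum and 7 in substantia nigra, and HET had 1 in each. The age difference in striatum went to 0 without them, without the 9 libraries with shifted markers and without both sets. Without the shifted libraries KO substantia nigra at 4 weeks had 2 calls, the test of striatum against the other regions went from 692 to 375, and striatal projection neuron markers in KO striatum at 4 weeks turned from lower to higher (adjusted p = 0.000878 when the tests of all comparisons that lose libraries are replaced, and 0.000842 when those of this comparison alone are). These alternatives were chosen after the data were seen, and fewer samples enter each. With an estimated correlation 0 of the 924 list tests passed, against 246 with the preset value.

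Leaving out each library in turn gave 362 fits. In KO the range was 1 to 105 in prefrontal cortex, 1 to 34 in somatosensory cortex, 1 to 3 in hippocampus, 346 to 880 in striatum, 1 to 176 in thalamus and 1 to 1 in substantia nigra at 4 weeks. At 12 weeks it was 1 to 5, 0 to 0, 1 to 4, 0 to 0, 1 to 5 and 0 to 1. In HET it was 1 to 53 in thalamus at 4 weeks, 0 to 1 in thalamus and somatosensory cortex at 12 weeks, and unmoved elsewhere. For the age difference it was 0 to 53 in striatum, 0 to 1 in thalamus and substantia nigra, and 0 to 0 elsewhere. The list count ran from 240 to 255. Akap11 in HET somatosensory cortex at 12 weeks ran from -0.51 to 0.09 and was above 0 only without WT 2, the highest WT library (239.3 CPM), where WT 1 and WT 3 at 14.3 and 14.6 CPM weigh more in the WT mean.

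Samples of different genotypes share replicate numbers, and the labels do not say that the numbers pair them. As a block, the number gave KO counts of 3 and 8 in prefrontal cortex at 4 and 12 weeks, 1 in somatosensory cortex at 4 weeks, 399 (207 up, 192 down) in striatum at 4 weeks and 1 in thalamus at 4 weeks, and 4 in HET thalamus at 12 weeks, and it moved no other count. Over 2000 genes, samples with the same number correlated from -0.45 to 0.39 after group means were removed, 31 of 111 pairs were best with their own number, and the numbers paired samples in 0 of 24 comparisons. With every library of striatum at 4 weeks thinned to the smallest total, 700 genes were called in KO against 725, and what depth limits was not tested in the other comparisons.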

Other observations

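The genes followed here were chosen after their values were seen, and the other splits of the samples were planned. Prkar1a, the regulatory subunit gene of PKA called in KO somatosensory cortex at 4 weeks, was lower with an unadjusted p < 0.05 in 8 of the 9 KO comparisons whose labels are not in question, with a mean log2 fold change of -0.18. In thalamus at 4 weeks it was at 521.3 ± 24.44 CPM in KO and 635.1 ± 13.41 in WT (-0.28, SE 0.05, adjusted p = 0.0682), and in prefrontal cortex at 12 weeks at 594.9 ± 46.29 and 720.8 ± 32.84 (-0.28, SE 0.06, adjusted p = 0.455). In striatum at 4 weeks it was at 583.5 ± 31.44 and 552.1 ± 19.04 (0.09, SE 0.05, adjusted p = 0.36). Adcy2, an adenylyl cyclase gene, was lower in 6 of the 9 and higher in 1.

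Igtp and Nlrc5, which are induced by interferons and act in antiviral defence and antigen presentation, were each higher with an unadjusted p < 0.05 in 6 of the 9 comparisons, with mean log2 fold changes of 0.47 and 0.62. Edn1 (0.69) and the glucose transporter gene Slc2a4 (0.62) were higher in 5, and Dkk3 (-0.50), Klf10 (-0.34) and Serpina3n (-0.36) lower in 5. In all, 93 genes had such a p in 1 direction in at least 4 of the 9 comparisons. The number expected without a change was not computed, and regions are not independent where they share animals: Gm16867 stayed in KO 1 and KO 4 at 4 weeks and in KO 5 at 12 weeks in every one of these regions that holds them. Red blood cell genes had median log2 fold changes of -3.266 in striatum, -3.477 in thalamus, -2.406 in somatosensory cortex and -2.352 in hippocampus in KO at 4 weeks (adjusted p = 0.000836, 0.000369, 2.5e-05 and 0.00222; adjusted p = 0.798, 0.785, 0.729 and 0.798 with an estimated correlation). The striatal call was lost without the shifted libraries (-3.073, adjusted p = 0.0752). The other 8 KO comparisons did not pass: -0.833 in prefrontal cortex and 1.114 in substantia nigra at 4 weeks, and at 12 weeks -0.609 in prefrontal cortex, -1.292 in somatosensory cortex, -1.424 in hippocampus, 1.056 in striatum, 1.412 in thalamus and -1.463 in substantia nigra.

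Each count of called genes was compared with 100 splits of the same libraries into groups of the same sizes, the real split among them. For KO striatum at 4 weeks 4 of the 100 splits had at least the 725 called genes. That is a share under 0.05 by itself, not adjusted for the 30 counts tested, so chance was not excluded. The highest other count of 2559 came with KO 2, KO 4, WT 4 and WT 6 against the rest, which points to a structure of the samples, and these were the 4 highest in cortical markers (4.96, 4.63, 0.99 and 3.93) of the KO and WT libraries. Elsewhere Akap11 was the only call or 1 of few, and a split that mixes genotypes loses the disrupted gene by design, so the splits say nothing on chance for other genes. With other calls beside Akap11 these were KO in prefrontal cortex at 12 weeks (2 real, 1 split, highest other 1), somatosensory cortex at 4 weeks (4, 2 splits, 10) and thalamus at 4 weeks (2, 3 splits, 852), and the counts without Akap11, which were not tested, were 1, 3 and 1. With Akap11 alone they were KO in prefrontal cortex at 4 weeks (1 real, 4 splits, highest other 2067), hippocampus at 4 weeks (1, 6 splits, 1584) and 12 weeks (1, 5 splits, 47), thalamus at 12 weeks (1, 2 splits, 1) and substantia nigra at 4 weeks (1, 3 splits, 278). The highest others of 2067, 1584, 852 and 278 point to a structure of the samples.

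With a real count of 0, all 100 splits had as many for KO at 12 weeks in somatosensory cortex (highest other 4), striatum (626) and substantia nigra (6). In each of these 3 the highest split was the one that placed the libraries with low Akap11 together. For striatum it set KO 2, KO 4, KO 5, WT 1 and WT 3 (15.3 to 24.5 CPM) against the rest (299.6 to 369.8 CPM). The 626 genes thus followed the Akap11 level and not the label. In HET, where every count of 1 was Akap11 and the same limit holds, the values were for prefrontal cortex at 4 weeks 1 real, 1 split, highest other 0, and at 12 weeks 1, 3 splits, 1. They were for somatosensory cortex at 4 weeks 1, 6 splits, 12, hippocampus at 12 weeks 1, 4 splits, 2, striatum at 4 weeks 1, 3 splits, 5, thalamus at 4 weeks 1, 4 splits, 9 and at 12 weeks 1, 8 splits, 382, and substantia nigra at 4 weeks 1, 2 splits, 1. The HET counts of 0 were met by all 100 splits, with highest others of 43 in hippocampus at 4 weeks and 1, 1 and 2 in somatosensory cortex, striatum and substantia nigra at 12 weeks. For the age difference in striatum 12 splits had at least the 1 real call (highest other 482), and in the other regions all 100 met the count of 0, with highest others of 0 in prefrontal and somatosensory cortex, 271 in hippocampus, 1192 in thalamus and 8 in substantia nigra.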
